A study of Mus musculus with 6 samples.

How the data were processed

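RNA from brainstem motor neurons of 3 WT and 3 SOD1 samples was measured on a mouse Affymetrix array. Per the labels' protocols, total RNA was amplified in 2 rounds of a T7-based reaction, which starts at the 3' end of transcripts. How the motor neurons were collected, the scanner settings and the algorithm that made the probe set values are not given in the sources used here. The deposited values are linear signal intensities, 1 per probe set and array, with no detection calls. They ran from 0.688 to 232137, and their 2% trimmed mean was 2500.02 on every array, so each array had been scaled to a common mean. A signal summarised from several probes compresses at the top of its range and is noisy at the bottom, and 2 rounds of amplification shorten the RNA, so probe sets far from the 3' end can read low.

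The table held 45101 probe sets, of which 64 were controls and were left out of the tests. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed and are unnamed here. Symbols were looked up through Entrez identifiers in a table of RefSeq genes (GRCm38.p6), where 34741 matched and 0 were updated. No coordinates are given.

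The array medians on the log2 scale ranged from 8.15 to 8.37 as deposited, a range of 0.23. They averaged 0.11 lower in SOD1 than in WT, at 8.24 against 8.35. Since the range exceeded 0.1, the limit set before the data were examined, the arrays were quantile normalised, and 16 was added before taking log2. Probe sets above the 40th percentile of mean log2 signal were kept, which left 27022. SOD1 was compared with WT with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison, the gene lists, the rule for naming genes and the alternatives, except the term for Xist, were chosen before the data were examined.

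Gene lists were tested with camera (preset correlation of 0.01) on the probe set with the highest mean for each gene, with adjustment over the 30 of 33 lists that had at least 5 genes tested. Counts of list members are given over all probe sets tested and adjusted over the list alone. The genes named were the 15 with the largest rise and the 15 with the largest fall among those past the threshold with 1 symbol, every Sod1 probe set, and up to 4 members of each list with the smallest p. Other members are named where a count needs them, which was decided after their values were seen. A background level per array was taken as the 95th percentile of 27 bacterial control probe sets, also chosen after seeing the data. It lay between 7.22 and 7.62 on the log2 scale.

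The alternatives were values as deposited, median centring, pseudocounts of 1 and 64, no filter or a filter at the 60th percentile, no variance trend or a robust one, array weights, the replicate number as a block, each array left out, the mean of a gene's probe sets, no probe sets shared between transcripts, other thresholds, an estimated correlation and fry. Array measures were compared with exact two-sided permutation tests, whose smallest p is 0.1 with 3 against 3. The 3' minus 5' difference was 4.66 ± 0.39 in WT and 4.68 ± 0.37 in SOD1 for Actb (exact permutation p = 0.9) and 3.72 ± 0.70 and 3.57 ± 0.26 for Gapdh (exact permutation p = 1; log2, SD, n = 3). Correlations between arrays, across probe sets, were 0.918 to 0.957 within groups and 0.901 to 0.937 between groups.

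The limma and camera steps were tested on simulated data for this comparison, with 200 of 27022 probe sets changed in each of 5 draws. The share of changed probe sets recovered was 29.0% for a log2 change of 1, 67.8% for 2, 90.0% for 3 and 99.2% for 4, and 7.73% of the calls were false. A list shifted by 0.5 was called in 5 of 5 draws, and 2 lists that had not been shifted were called. The simulated probe sets varied independently of each other. In the data the estimated correlation was 0.443 for the microglial list and 0.548 for the interferon list. The simulation therefore does not show how often camera with the preset correlation calls such lists falsely. Figures were drawn with matplotlib 3.10.9.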

Results

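Gene expression was measured in RNA from motor neurons of the mouse brainstem, the neurons that send their axons to muscle. The 6 arrays fall into 2 genotypes with 3 RNA samples each, wild type (WT) and SOD1. SOD1 mice are named for the gene of copper-zinc superoxide dismutase, and which change of that gene they carried, and their age, are not given in the sources used here. The median signal lay between 267 and 315 on the 6 arrays, and the number of arrays limits the precision. Nothing in the labels says that the 3 samples of a group came from separate animals, so the p-values measure only the spread between these samples, part of which may be technical. SOD1 replicate 3 differed from SOD1 replicates 1 and 2 in Xist and the Y-linked genes, and all 3 WT arrays were like SOD1 replicate 3. Xist averaged 12.83 and 12.91 (log2 signal) in SOD1 replicates 1 and 2, 5.71 in SOD1 replicate 3 and 5.76 to 7.07 in WT. Sex may thus differ between the groups. The main comparison has no term for it, so genotype and sex are partly confounded in it. Changes are given as log2 fold changes, SOD1 minus WT, ± SE with n = 3 arrays per group, from values to which 16 was added, which understates the change of low genes.

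Sod1 itself was read by 5 probe sets, of which 4 were kept by the filter, and none of these passed the test. The probe set with the highest signal gave 16.51 ± 0.17 in WT and 16.78 ± 0.08 in SOD1 (log2 signal, SD, n = 3), a difference of 0.27 ± 0.10 (limma, adjusted p = 0.258). The difference depended on the scaling, at 0.46 (adjusted p = 0.1) with values as deposited and 0.57 (adjusted p = 0.101) with median centring. The other 3 kept differed by 0.06 ± 0.08, -0.38 ± 0.42 and -0.81 ± 0.41. The fifth, below the filter and at the background level on 1 WT and 2 SOD1 arrays, differed by -0.29 ± 0.79. A mouse probe set need not measure a human SOD1 transcript, so these values do not check the genotype labels.

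Genes of microglia, the resident macrophages of the brain, rose in the SOD1 samples. Tyrobp, a signalling adaptor of myeloid receptors, went from 9.67 ± 1.36 to 14.15 ± 0.71 (log2 signal, SD, n = 3), 22.3-fold (log2 change 4.48 ± 0.58, adjusted p = 0.0267). Cst7, a cysteine protease inhibitor, rose by 5.03 ± 0.83, Lgals3, which encodes galectin-3, by 4.47 ± 0.75, and Ly86 by 3.98 ± 0.63. Ctss, a lysosomal protease of these cells, rose 6.62-fold from an already high WT level of 12.71 ± 0.79. Of the 19 microglial and myeloid markers tested, 7 rose over all genes and 16 rose when adjusted over the list alone, and all 19 had a positive estimate, with a median log2 change of 2.87. The camera test called the list higher (adjusted p = 2.56e-20), against adjusted p = 0.479 with an estimated correlation. Through the adjustment, all 12 called lists and some lists not called share that second value, so it does not rank them. For Cst7 and for Lgals3, 2 of the 3 WT arrays were at the background level, and for Ptprc 1 was.

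Further genes with the largest rises were Tent5c (3.63 ± 0.55, with 2 WT arrays at background), Pycard, an inflammasome adaptor (3.04 ± 0.43), Fcgr3, an immunoglobulin receptor (3.13 ± 0.48), Ptprc, the leukocyte antigen CD45 (2.98 ± 0.46), Itgb2, a leukocyte integrin (2.96 ± 0.45, with 1 WT array at background), Slc14a1, a urea transporter (2.59 ± 0.39), and Hpgd, which degrades prostaglandins (2.00 ± 0.30). Complement genes were uneven. C1qa, a subunit of the first complement component, rose by 3.00 ± 0.37, and when adjusted over the list alone 5 of the 10 complement genes rose, among them C1qb (2.36 ± 0.56) and C1qc (2.80 ± 0.62), while 1 passed over all genes. The list had a median of 0.38 and was called higher (camera, adjusted p = 0.0280), against adjusted p = 0.479 with an estimated correlation. Without SOD1 replicate 1 its median was -0.07 (adjusted p = 0.349), without WT replicate 3 it was 0.41 (adjusted p = 0.0734), without SOD1 replicate 2 it was 0.24, and without SOD1 replicate 3 it was 0.65. The call was also lost with no filter (median -0.02) and with a filter at the 60th percentile (0.01), and it was made in 14 of 19 settings.

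Some astrocyte genes were also higher in SOD1. Gfap, the intermediate filament of astrocytes, rose 10.4-fold (3.38 ± 0.47, adjusted p = 0.0317), and Aqp4, a water channel, rose 3.05-fold (1.61 ± 0.22, adjusted p = 0.0317). Of 16 astrocyte markers, 2 rose over all genes and 6 when adjusted over the list alone, the latter including Acsbg1 (0.92 ± 0.28) and Gja1 (0.60 ± 0.17). The estimate was positive for 12 of the markers and negative for 4. The list median was 0.31 (camera, adjusted p = 0.00122), against adjusted p = 0.479 with an estimated correlation, and without WT replicate 3 it was 0.20 (adjusted p = 0.0529). Oligodendrocyte markers passed only when adjusted over the list alone, where 6 of 14 rose, against 0 over all genes. Their estimate was positive for 11 and negative for 3. Among the 6 that rose, Ugt8a changed by 1.01 ± 0.25, Cldn11 by 1.08 ± 0.31 and Cnp by 0.44 ± 0.11. The oligodendrocyte list had a median of 0.49 (camera, adjusted p = 0.000318), against adjusted p = 0.479 with an estimated correlation.

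**Figure D1:**
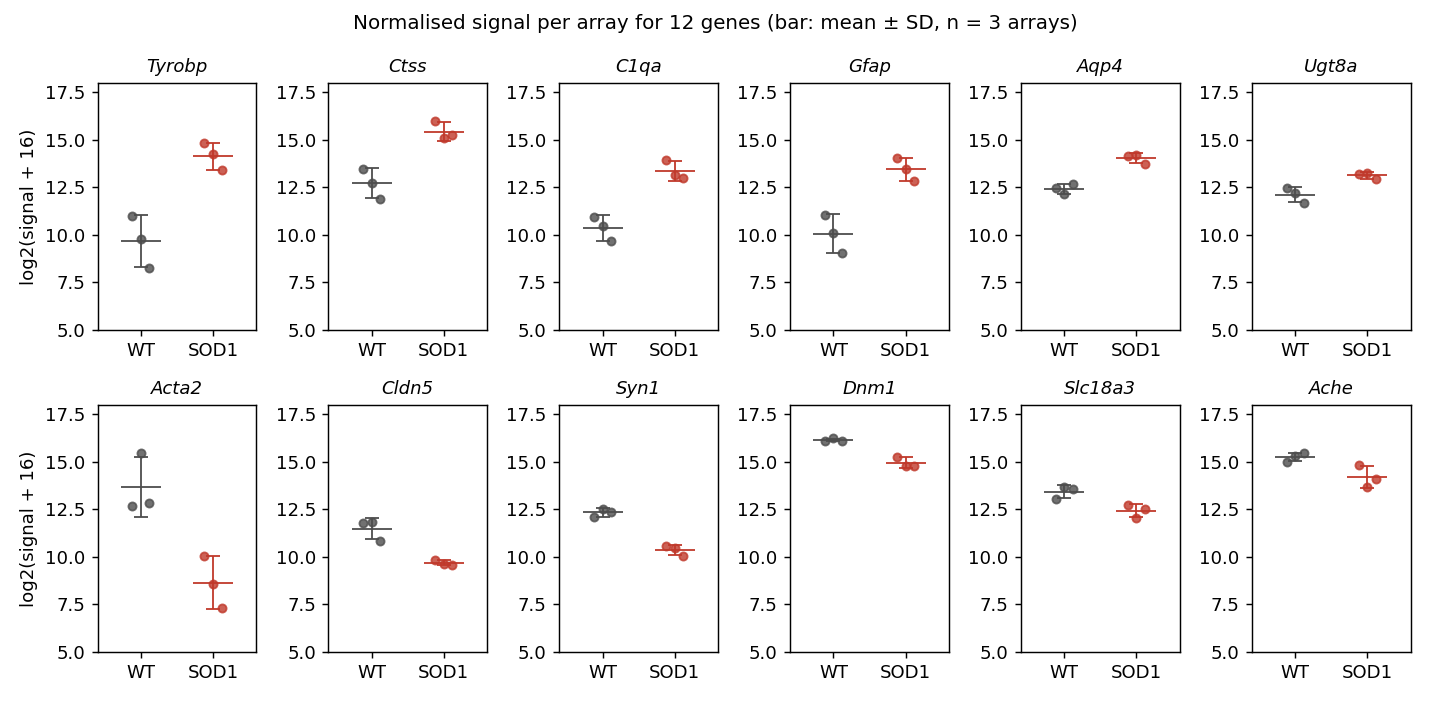
Normalised signal on the log2 scale (vertical axis) on each array of the WT (grey) and SOD1 (red) groups for 12 genes, points being arrays and bars the mean ± SD of 3 arrays. Tyrobp, Ctss, C1qa, Gfap, Aqp4 and Ugt8a lie higher on the SOD1 arrays, and Acta2, Cldn5, Syn1, Dnm1, Slc18a3 and Ache lie lower.

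Genes of blood vessels and smooth muscle fell in the SOD1 samples. Acta2, smooth muscle actin, went from 13.66 ± 1.57 to 8.64 ± 1.38 (log2 signal, SD, n = 3), 32.4-fold lower (limma, adjusted p = 0.0327), and Tpm2, a muscle tropomyosin, fell by 3.20 ± 0.49. Col4a1, a basement membrane collagen, fell by 1.45 ± 0.24, although a second probe set of the gene gave 0.02 ± 0.58. Of 14 endothelial and mural markers, 1 fell over all genes and 5 when adjusted over the list alone, the latter including the tight junction gene Cldn5 (-1.80 ± 0.34) and Vwf, von Willebrand factor (-2.69 ± 0.51). All 14 had a negative estimate, with a median of -0.75 (camera, adjusted p = 1.93e-05), against adjusted p = 0.479 with an estimated correlation. Without SOD1 replicate 1 the median was -1.14, and with a filter at the 60th percentile it was -1.28. It was nearer to 0 without SOD1 replicate 3 (-0.51) and without WT replicate 1 (-0.52).

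Several neuronal genes fell. Syn1, a synaptic vesicle phosphoprotein, fell by 1.98 ± 0.28, Syt2, a calcium sensor of transmitter release, by 0.99 ± 0.14 and Dnm1, the dynamin of vesicle recycling, by 1.20 ± 0.14 from a WT level of 16.15 ± 0.07 (adjusted p = 0.0221). A second Dnm1 probe set, of low signal, gave 0.02 ± 0.59. Of 25 synaptic vesicle genes, 2 fell over all genes and 3 when adjusted over the list alone, the added gene being Rims1 (-0.79 ± 0.22). The list median was -0.18 (camera, adjusted p = 0.0212), against adjusted p = 0.479 with an estimated correlation. It was called neither with values as deposited (median -0.09) nor with median centring (0.01), and in 13 of 19 settings in all. Without WT replicate 3 the median was -0.03 (adjusted p = 0.156), and without SOD1 replicate 2 it was -0.11.

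Other genes with large falls were Preb (-2.29 ± 0.32), Marveld1 (-2.16 ± 0.35), Pqbp1 (-1.92 ± 0.20), the histone methyltransferase gene Kmt2a (-1.77 ± 0.30), Podxl2 (-1.57 ± 0.24), the transcription factor gene Foxp1 (-1.56 ± 0.24), Exoc4 of the exocyst (-1.43 ± 0.22), Flii (-1.42 ± 0.20), the semaphorin gene Sema7a (-1.39 ± 0.22) and Camta2 (-1.37 ± 0.21). Other probe sets of some of these genes moved less. A second probe set gave -0.24 ± 0.21 for Pqbp1, -0.29 ± 0.45 for Kmt2a and -0.18 ± 0.23 for Exoc4. Those of Preb gave -0.78 ± 0.28 and -0.09 ± 0.41, and those of Marveld1 kept by the filter -0.52 ± 0.54 and -0.50 ± 1.10. Over the genes with the largest changes, 21 of 25 other probe sets kept by the filter had the same sign, and the 4 with the opposite sign were those of Col4a1 and Dnm1 given above, 1 of Foxp1 (0.02 ± 0.39) and 1 of Exoc4 (0.12 ± 0.66), none at an unadjusted p under 0.05 by limma.

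Markers of the motor neurons themselves did not shift as a group. Of 18 tested, 0 passed over all genes, and when adjusted over the list alone 3 fell, Ache, acetylcholinesterase (-1.06 ± 0.25), Slc18a3, the vesicular acetylcholine transporter (-0.995 ± 0.25), and Nefm, a neurofilament subunit (-0.33 ± 0.10). Nefm depended on the scaling, at -0.16 with values as deposited and -0.06 with median centring, where Ache was at -0.90 and Slc18a3 at -0.92. The largest change of the list was a rise, that of Uts2, a urotensin gene (2.02 ± 0.74, limma, adjusted p = 0.0697 over the list alone), and Mmp9 was at -0.80 ± 0.26, Slc5a7 at 0.72 ± 0.44, Chat at -0.40, Nefl at 0.01, Chodl at -0.04 and Isl1 at 0.23, none past either threshold. The list median was -0.02 (camera, adjusted p = 0.555), and it was 0.03 with values as deposited and 0.13 with median centring. Markers of other neuron types had a median of 0.02 over 13 genes (adjusted p = 0.637), with 0 past either threshold. Of 7 Hox genes tested, 0 passed either threshold (list adjusted p = 0.671), and the 7 oligodendrocyte precursor markers also had 0 (adjusted p = 0.873). Blood markers, with 1 gene tested, and choroid plexus and ependymal markers, with 4, were too few for the list test. The 1 blood gene, S100a8, was at -2.77 and did not pass over all genes (limma, adjusted p = 0.311). With 1 gene, its p adjusted over the list alone is the unadjusted one (0.0373), its value was 12.64 on WT replicate 2 against 7.86 and 7.46 on the other WT arrays, and 2 SOD1 arrays were at the background level. Of the choroid plexus and ependymal genes, 0 of the 4 passed either way.

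Voltage-gated ion channel genes had a median of -0.32 over 32 genes (camera, adjusted p = 0.0212), against adjusted p = 0.479 with an estimated correlation. None passed over all genes, and when adjusted over the list alone 1 fell, the sodium channel gene Scn8a (-1.01 ± 0.21). The call was lost without WT replicate 1 (median -0.24, adjusted p = 0.129), WT replicate 3 (-0.15, 0.108) or SOD1 replicate 3 (-0.17, 0.120). Neurotrophic factors and receptors had a median of -0.45 over 17 genes (adjusted p = 0.0322), against adjusted p = 0.479 with an estimated correlation, with 0 past the threshold over all genes or adjusted over the list alone. Ntrk2, the receptor of brain-derived neurotrophic factor, was at -0.65 ± 0.18. This call was lost without WT replicate 2 (-0.27, 0.0780), WT replicate 3 (-0.49, 0.108) or SOD1 replicate 3 (-0.21, 0.547), and it was made in 13 of 19 settings.

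Genes of axonal transport and the cytoskeleton had a median of -0.03 over 37 genes (camera, adjusted p = 0.0379), and glycolysis genes a median of -0.13 over 13 genes (adjusted p = 0.0453), both with adjusted p = 0.479 with an estimated correlation and both with 0 genes past the threshold over all genes or adjusted over the list alone. The tau gene Mapt was at -0.85 ± 0.24. The axonal transport list was lost without WT replicate 3 (-0.08, adjusted p = 0.332), SOD1 replicate 2 (-0.02, 0.112) or SOD1 replicate 3 (-0.09, 0.0900), and had medians of -0.14 without WT replicate 1 and -0.11 without SOD1 replicate 1. The glycolysis list was lost without WT replicate 2 (-0.11, 0.0780), WT replicate 3 (-0.08, 0.189), SOD1 replicate 2 (-0.14, 0.0628) or SOD1 replicate 3 (-0.16, 0.0848). The sign of both medians turned with the scaling. With values as deposited they were 0.0095 for axonal transport and 0.04 for glycolysis, and with median centring 0.12 and 0.14, none of them called. Axonal transport was called in 8 of 19 settings and glycolysis in 6.

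Interferon and MHC class I genes had a median of 1.02 over 21 genes, and camera called the list higher in SOD1 (adjusted p = 2.47e-05), against adjusted p = 0.479 with an estimated correlation. The SOD1 arrays differed among themselves, with list means of 10.89, 10.24 and 12.18 (log2 signal) on replicates 1, 2 and 3, against 10.42, 10.46 and 9.30 in WT. None of the genes passed over all genes, and 5 rose when adjusted over the list alone, among them B2m, the light chain of MHC class I (1.01 ± 0.22), H2-K1, an MHC class I heavy chain (1.31 ± 0.31), and the immunoproteasome gene Psmb8 (1.90 ± 0.58). SOD1 replicate 3 had the highest value of the 6 arrays for 16 of the 21 genes. Without it the list median was 0.30 (adjusted p = 0.0130), and without SOD1 replicate 2 it was 1.54. Cytosolic ribosomal protein genes had a median of 0.18 over 41 genes (camera, adjusted p = 1.06e-05), against adjusted p = 0.479 with an estimated correlation, with 0 genes past the threshold over all genes or adjusted over the list alone. Rps14 was at 0.41 ± 0.11 and Rpl22 at 0.46 ± 0.14. The ribosomal median depended on the scaling, at 0.31 with values as deposited and 0.42 with median centring, and it was 0.28 without SOD1 replicate 1.

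**Figure D2:**
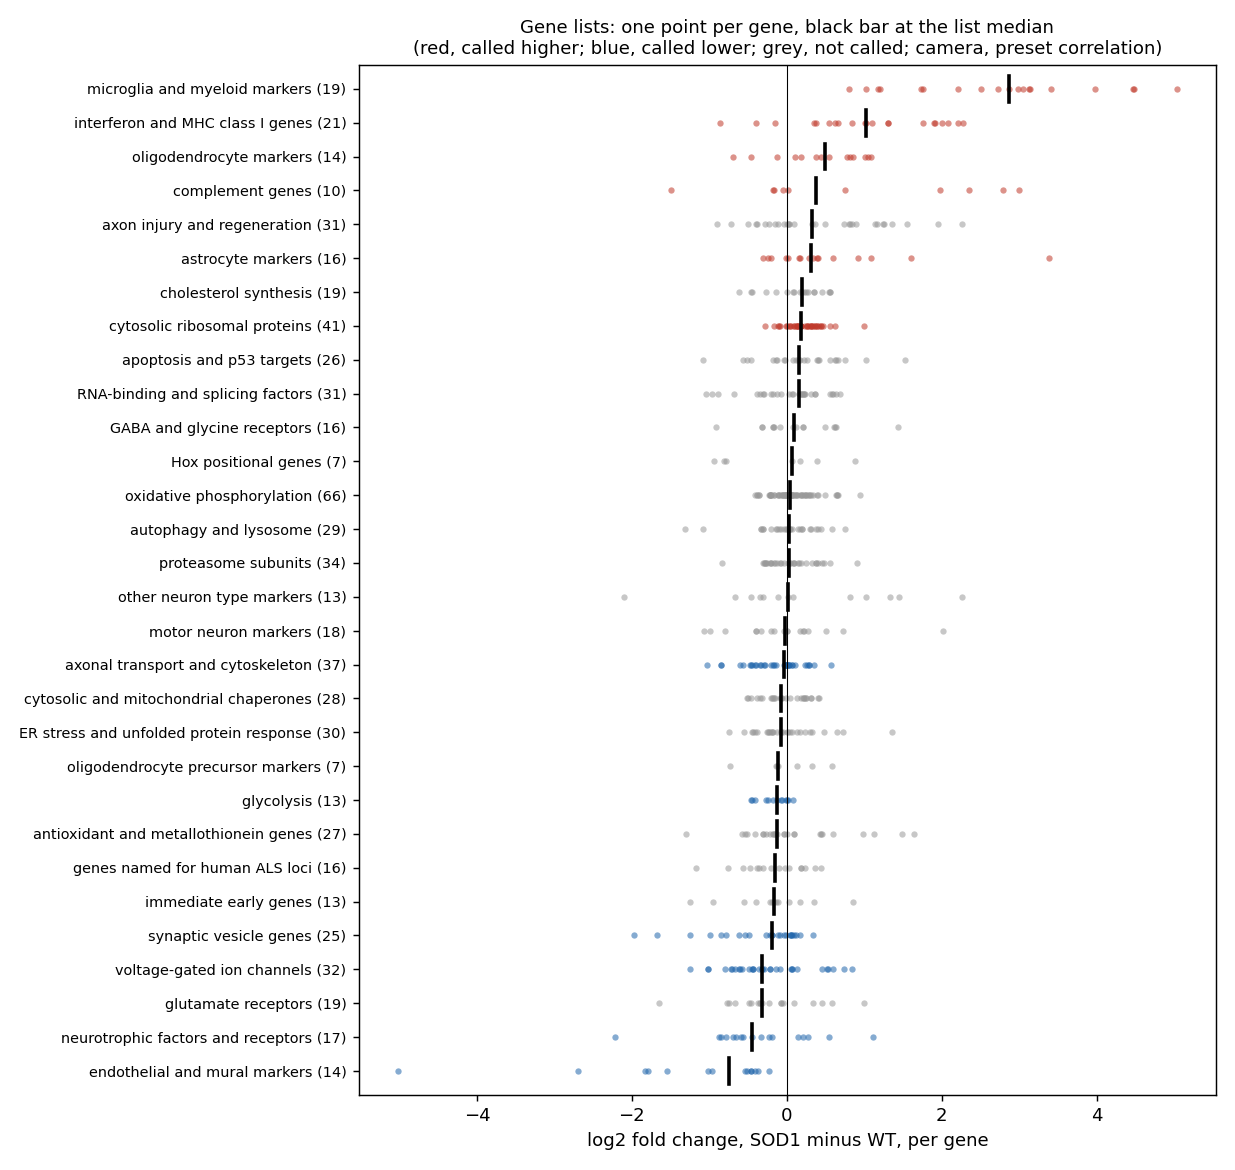
Log2 fold change, SOD1 minus WT (horizontal axis), of each gene in the 30 gene lists tested, with the number of genes in brackets, points being genes and black bars list medians. The 19 microglial and myeloid markers all lie above 0, with a median of 2.87, and the 14 endothelial and mural markers all lie below it, with a median of -0.75; no call was kept with an estimated correlation.

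The remaining lists were not called by camera in the main setting, and 0 of their genes passed over all genes. Axon injury and regeneration genes had a median of 0.33 over 31 genes (adjusted p = 0.153), and adjusted over the list alone 2 rose, Tubb2b (1.25 ± 0.35) and Chl1 (0.84 ± 0.23), and 1 fell, Basp1 (-0.72 ± 0.19). The axon injury list was called without WT replicate 1 (median 0.17, adjusted p = 0.0258) and without SOD1 replicate 2 (0.31, 0.0241), against adjusted p = 0.528 and 0.522 with an estimated correlation. Genes named for human ALS loci had a median of -0.15 over 16 genes (adjusted p = 0.0778), and adjusted over the list alone 4 fell, among them Atxn2 (-1.17 ± 0.25). The ALS list was called lower without SOD1 replicate 1 (median -0.33, adjusted p = 0.0421, against 0.564 with an estimated correlation), and with median centring its median was 0.03. Adjusted over the list alone, the metallothionein genes Mt1 (1.13 ± 0.32) and Mt2 (1.49 ± 0.41) and the gene Nfe2l2 rose and Gpx1, a glutathione peroxidase, fell (-0.58 ± 0.16) among 27 antioxidant and metallothionein genes (list adjusted p = 0.933). Of 29 autophagy and lysosome genes (adjusted p = 0.739), 1 rose, Ctsl, and 1 fell, Lamp2 (-1.31 ± 0.23), again adjusted over the list alone.

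For the other 10 lists, 0 genes passed adjusted over the list alone. ER stress genes had a median of -0.07 over 30 genes (adjusted p = 0.671) and chaperones -0.07 over 28 (adjusted p = 0.973). The medians were 0.03 for proteasome subunits (adjusted p = 0.532), 0.04 for oxidative phosphorylation (adjusted p = 0.0769), 0.16 for apoptosis and p53 targets (adjusted p = 0.188) and 0.20 for cholesterol synthesis (adjusted p = 0.134). They were -0.17 for immediate early genes (adjusted p = 0.364), -0.33 for glutamate receptors (adjusted p = 0.515), 0.10 for GABA and glycine receptors (adjusted p = 0.555) and 0.15 for RNA-binding and splicing factors (adjusted p = 0.602). With values as deposited, camera called oxidative phosphorylation (median 0.22) and proteasome subunits (0.05) higher, and with median centring it called both (0.33 and 0.16) and chaperones (0.15) higher. With an estimated correlation it called 0 lists in either setting (lowest adjusted p = 0.385 and 0.451). Leaving out 1 array made camera call cholesterol synthesis higher (without WT replicate 3, median 0.27, adjusted p = 0.0284, and without SOD1 replicate 2, 0.27, 0.0388) and oxidative phosphorylation (without SOD1 replicate 1, 0.05, 0.0494), against adjusted p = 0.645, 0.641 and 0.564 with an estimated correlation. Camera also called cholesterol synthesis with array weights (0.26, 0.0465) and oxidative phosphorylation without probe sets shared between transcripts (0.07, 0.0304). With an estimated correlation these had adjusted p = 0.618 and 0.454. The medians of ER stress (0.05) and antioxidant genes (0.04) were positive with median centring. The median and the test differed in sign for chaperones, oligodendrocyte precursors and Hox genes, and the median and the mean for antioxidant, autophagy and Hox genes.

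Xist, the RNA of the inactive X chromosome, was at 12.83 and 12.91 (log2 signal, mean of its probe sets) in SOD1 replicates 1 and 2, against 5.71 in SOD1 replicate 3 and 5.76 to 7.07 on the 3 WT arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty averaged 5.83 and 5.87 on those 2 SOD1 arrays and 9.87 to 10.57 on the other 4 arrays. Adjusted over the list alone, 1 of the 4 sex chromosome genes rose (Xist) and 2 fell (Kdm5d and Uty), with 0 past the threshold over all genes. With a term for the arrays of high Xist, chosen after seeing the data, 65 probe sets passed, 8 of them among the 50 of the comparison without it. That fit sets SOD1 replicate 3 alone against the 3 WT arrays, and this single sample is assumed to vary like the others. Its list calls rest on that 1 array, and with an estimated correlation camera called 0 lists in it (lowest adjusted p = 0.444).

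In all, 50 of 27022 probe sets passed an adjusted p of 0.05 by limma, 17 higher and 33 lower in SOD1, with 3962 at an unadjusted p under 0.05 where 1351 are expected by chance. The other splits of the arrays into 3 and 3 gave 609 to 1952 at that limit. The excess may include differences of sex, which is partly confounded with genotype. The groups did not overlap for 20.3% of probe sets, against 10% by chance. By gene, 36 of 13123 passed, 16 higher and 20 lower. Without WT replicate 1 the count was 9 (6 higher and 3 lower), without WT replicate 2 it was 0 (2659 at an unadjusted p under 0.05), without SOD1 replicate 1 it was 35 (2 higher and 33 lower), without SOD1 replicate 2 it was 6 (0 higher), without SOD1 replicate 3 it was 29 (11 higher and 18 lower), and without a variance trend limma called 0 (3248 at an unadjusted p under 0.05). Of the 30 gene lists, camera called 12 with the preset correlation, 6 without WT replicate 3, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05 and fry also called 0 one way.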

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

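The comparison of the control probe sets was chosen only after the data were seen. Of 33 control probe sets above the background level on all arrays, which were left out of the tests of genes, 5 were higher on every SOD1 array than on every WT array and 0 were lower on every one. Their mean differences, SOD1 minus WT on the log2 scale of the deposited values, were 0.824 for the 3' probe set of 18S ribosomal RNA, 1.01 for its middle probe set, 0.379 for the 5' probe set of CreX, 0.313 for the 5' probe set of bioB and 0.176 for the mouse B2 repeat. CreX and bioB are bacterial or phage transcripts used as controls, so their differences are not of mouse gene expression. A technical difference between the 2 groups of arrays was not tested and stays open. With 3 arrays against 3, chance gives complete separation one way or the other for 10% of probe sets. The groups of 3 were too small for a test of single outlying arrays.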

How the results depend on the processing

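The Xist term was chosen only after the data were seen. The 50 probe sets became 44 with values as deposited, 41 with median centring (19 higher and 22 lower, against 17 and 33), 87 with pseudocount 64, 106 with a filter at the 60th percentile, 0 with no variance trend (limma, 3248 at an unadjusted p under 0.05), 100 with array weights, 190 at an adjusted p of 0.10 and 1176 at an unadjusted p of 0.01 with 1.5-fold. Leaving out 1 array gave 0 to 75 probe sets and 6 to 13 lists. The 12 lists became 7 with the stricter filter and 0 with an estimated correlation or fry one way; fry in either direction called 20. Replicate numbers did not pair the samples (correlations of deviations 0.03, -0.04 and -0.01), and the replicate block gave 76 probe sets, 40 of them shared, and 10 lists. The axonal transport median was 0.0095 with values as deposited and 0.12 with median centring, and that of glycolysis 0.04 and 0.14; the cause was not tested. All 31 called named genes kept their sign wherever measured. With an array left out or the Xist term this was nearly fixed in advance, since the groups did not overlap for any of these genes. The filter, variance and replicate block settings do not alter the change itself. Fewer kept their call: 0 without WT replicate 2 or with no variance trend, 1 without SOD1 replicate 2, 4 with the Xist term, 7 without WT replicate 1, 9 without SOD1 replicate 3, 12 without SOD1 replicate 1 and 15 with the mean of a gene's probe sets. Without probe sets shared between transcripts, the smallest change was 0.127 of its value. Sod1 lay between 0.18 and 0.57 (median centring) in 17 settings and passed in 0. Microglial, oligodendrocyte, endothelial and mural, interferon and ribosomal lists were called in all 19 settings other than the estimated correlation and fry. Low signal limits genes near background.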

Other observations

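The tests of a lower motor neuron share, sex, RNA integrity, a single array and both sexes in the group, and the correlation and splits of the second gene list, were chosen only after the result was seen. Those of the median of that list, a mislabelled array and the splits for probe sets and list calls were set before their own values were seen. The fall of vessel genes and the Xist values, which the second list and the mislabelled array address, were known by then.

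Single genes stood apart on single arrays, and those named here were chosen after their values were seen. On SOD1 replicate 3, the interferon-induced genes Usp18 and Rsad2 were at 12.60 and 13.90 (log2 signal), 4.71 and 5.60 above the mean of the other 5 arrays, of which 1 was at the background level for each gene. Npy, a neuropeptide, was at 13.89 there, 5.59 above the mean of the others. Gad1, an enzyme of GABA synthesis, was at 11.48 there, and 3 of the other 5 arrays were at the background level. S100a8, a neutrophil gene, was at 12.64 on WT replicate 2 and at 7.86 or less on every other array, and the choroid plexus gene Ttr was highest on WT replicate 1, at 13.21.

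Microglial genes were higher in SOD1, and so were 12 of 16 astrocyte markers by estimate, 2 of them past the threshold over all genes. A lower share of motor neuron RNA would raise the markers of every other cell type alike. The mean of the microglial markers exceeded that of the endothelial and mural markers by 4.0 ± 0.34 (log2, SE over arrays, n = 3 per group), 2.72 against -1.28. That gap alone cannot decide this, since it had been seen before the test was chosen. Less vessel tissue, left open below, would also lower the endothelial and mural markers by itself. The mean changes of astrocyte (0.54) and oligodendrocyte markers (0.42) were below 2.72 too, and had also been seen before. They go against a lower share as the whole cause of the microglial rise but do not decide it. The WT mean was above 11 for 11 of 16 astrocyte markers, against 2 of 19 microglial ones. A signal that compresses at the top of its range may keep such markers from rising alike. Sex may contribute, since 2 SOD1 arrays had high Xist. SOD1 replicate 3, with low Xist, lay above all 3 WT arrays for 18 of 19 microglial markers, but 1 array excludes nothing, so sex stays open. The 3' minus 5' ranges of the groups overlapped for 2 of 2 genes (Actb and Gapdh), which cannot exclude a difference in RNA integrity with 3 arrays each. Of the 3 probe sets of 18S ribosomal RNA, the 3' and middle ones separated the groups (0.82 and 1.01 higher in SOD1). Their exact permutation p was 0.1 each, the smallest possible with 3 arrays each. The 5' one did not separate the groups (0.36, exact permutation p = 0.4), so RNA integrity and the genotype both stay open.

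Endothelial and mural genes were lower in SOD1. A single WT array with more vessel tissue is argued against for the list as a whole, since its median stayed at -0.51 or below whichever array was left out. That median does not speak for the smooth muscle genes Acta2 and Myl9, which were highest on WT replicate 2. Acta2 was at 15.48 there, against 12.69 and 12.81 on the other WT arrays, and Myl9 at 12.25, against 9.74 and 10.3. Acta2 reached at most 10.06 on the SOD1 arrays. How much WT replicate 2 adds to these falls stays open. SOD1 replicate 3 lay below all 3 WT arrays for 13 of 14 markers, which leaves sex open for the same reason. A second list of 20 meningeal fibroblast and smooth muscle genes, of which 17 were tested and 0 are in another list, had a median of -1.56. This lay at percentile 0 of 10000 random lists matched on mean level, which met the prediction set in advance for less vessel and meningeal tissue. Random lists ignore that these genes move together (estimated correlation 0.351), and camera with that correlation gave p = 0.125. Of the 10 splits of the arrays, 2 gave a median as far from 0, the real one included, the other at 1.64. All 17 were lower and 3 fell when adjusted over the list alone, among them Col1a2 (-2.58 ± 0.67), with 0 past the threshold over all genes. Less vessel and meningeal tissue in the SOD1 samples stays open, and its abundant genes Ptgds (16.32 in WT, 15.92 in SOD1) and Dcn (14.85 and 14.21) differed by less; a difference in vessels between the genotypes was not tested apart from it.

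Xist was high in SOD1 replicates 1 and 2. Xist and the Y-linked genes lay on opposite sides in 6 of 6 arrays, as mice of both sexes in the SOD1 group may give; pools of animals were not tested. Were SOD1 replicate 3 a mislabelled WT sample, it would lie nearer to WT for most of the 29 probe sets called without it. SOD1 replicate 3 lay closer to the other SOD1 arrays for 62.1% of them (18), short of the 90% set in advance for excluding this. Without SOD1 replicate 3, however, high Xist goes with the SOD1 label on every array. Probe sets that follow sex were not taken out of the 29, and there it would lie near WT under either label. The shortfall therefore cannot tell a wrong label from sex. Other values argue against a WT sample: its mean over the microglial markers was 10.96, against 8.73 ± 0.83 in WT (SD, n = 3), over the endothelial and mural markers 8.86 against 10.87 ± 0.34, and Gfap was at 12.82, against 9.03 to 11.05. These lists and Gfap were picked after their values on all 6 arrays, this one included, were seen. The markers of a list also move together, so these amount to few independent values and a wrong label stays open. With each array held out in turn, at an unadjusted p under 0.001 by limma, the share closer to its own group ran from 51.8% (SOD1 replicate 1) to 83.3% (WT replicate 2). It was 71.8% for SOD1 replicate 3, where the same limit from sex holds. No array reached 90% here, so a rightly labelled array may also fall short of that limit. SOD1 replicate 1 also correlated more with WT replicates 1 and 2 (0.937 and 0.932) than with SOD1 replicates 2 and 3 (0.926 and 0.929).

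There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. Only 1 of them, the real one, gave as many as 50 probe sets, the highest of the others giving 0. Only 1, again the real one, gave as many as 12 gene lists, the highest of the others giving 10.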
